A study of mouse metagenome with 116 samples.

How the data were processed

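Per the labels, total DNA was extracted from gut contents by bead-beating in phenol-chloroform, sheared, ligated to barcoded adapters, size-selected, amplified by PCR and sequenced as single reads of 50 bases on an Illumina MiSeq. The data comprise 116 libraries from 34 mice in 2 sets of 56 and 60 libraries. All per-sample columns of both tables were used.

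The authors deposited 1 table per set. Per the file headers and row names, each column holds the share of a library assigned to each of 13 species and the library's total raw count. The deposited shares are fractions that add up to 1 in every library, and the deposited totals are whole read counts. The aligner, the rule for assigning reads to species and the kind of normalization are not given in the sources used here. The shares are not read counts divided by the total: among 6 libraries of 2 to 10 reads, 1 of 28 shares above 0 came within 0.01 of a whole number of reads, and a library of 4 reads holds 25.9% B. caccae and 74.1% E. fergusonii. A legend in the tables states that some samples were left out of the authors' final analysis, but the marks that show which are not in the text form of the tables, so every library was kept. Since each set was normalized in its own table, levels in set 1 and set 2 are set side by side at most, and were not tested against each other. No pair of the 6670 pairs of libraries had identical shares.

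Groups follow the labels for community, strain, sex, diet, gut site and mouse number. Communities were read from the species names, because the strain numbers in the labels run on from sample to sample. The labels give no cage, isolator, run or date, so no such batch could be examined, and mice of a group that shared an isolator would be confounded with it.

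Depth ranged from 1 to 432854 reads per library. A library with no reads of a species allows a share of up to that of 3 reads, and shares of single libraries carry 95% Wilson intervals with the total as n. These intervals and limits are approximate for normalized shares and cover counting error only. Libraries under 1000 reads numbered 24, and 15 held fewer than 50.

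Species were compared with limma 3.58.1 in R 4.3.3 on the log2 of the share plus 0.0001, with 1 fit per gut site over all groups of a set, eBayes without trend and without the robust option, and two-sided tests. p-values were adjusted by Benjamini-Hochberg over all species and sites of a comparison, with a threshold of 0.05. A species listed at 0 in all libraries of a fit at a site was not tested there. A species at 0 in both groups compared but not in another group of the fit was tested and entered the adjustment. For the communities, each of the 5 core species was divided by the sum of the 5, because adding species lowers every share of the whole. C. sporogenes was compared between the 6- and 13-species mice in a single test. Gut sites were compared with the cecum within mice, with mouse as a fixed block. Sums of the 8 added species, Bacteroidetes, Firmicutes and Proteobacteria were fitted as further features and adjusted over 4 sums and 3 sites. Whole communities in the cecum were compared by the R2 of the groups on Bray-Curtis distances, with exact permutation over all splits of the mice, one-sided by construction, and adjusted over the 8 cecal tests.

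Comparisons, tests, thresholds, alternatives and the rule for naming species were chosen before the data were examined. Species past the threshold are named, at most the 5 with the largest log2 difference per site, and C. sporogenes and the 4 sums in every comparison they enter.

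The alternatives were a pseudocount of 0.001 or 1e-05, a minimum mean share of 0.1%, centred log-ratios, shares of the whole community in place of the core, a ratio to the core, fitting only the groups compared, adjustment within each site, 1 fit over all sites with mouse as a random block, exact permutation or sign-flip tests, mouse number as a block across groups, other distances and sites for R2, and leaving out each mouse in turn. A restriction to libraries of at least 1000 reads was added after seeing the data, as were group means without a library that moved them by more than 1.5 times. Other splits of the mice into groups of the same sizes were fitted in the same way, up to 100 per comparison with a fixed seed.

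The fits were tested on simulated data, 100 data sets each, drawn from the means and log2 spreads of the real libraries of at least 1000 reads. Counting error at low depth was not simulated, and the changed species was drawn from 9 of the more abundant ones (C. aerofaciens or E. rectale for the communities), so the figures hold for deep libraries. A 4-fold change in 1 species was recovered in 92 of 100 data sets for diet in NMRI males, 83 for diet in C57BL/6J males, 96 for sex, 85 and 89 for strain on choline minus and plus, 50 for the 6- against 5-species comparison and 100 for site in set 2. A 2-fold change was recovered in 34, 26, 48, 34, 44, 48 and 99. For site in set 2, every site was drawn from the cecal libraries, without differences between mice. The change was made and scored in the distal large intestine, so those figures do not describe calls in the distal small intestine. Between groups, 0.529% to 0.765% of the tests of unchanged species were called beside a 2-fold change. Beside a 4-fold change it was 2.97% to 4.35%. For site in set 2 the figures were 7.04% and 20.7%, and shares that add up to 1 shift the other species when 1 changes. In 500 data sets without a difference the R2 test gave p under 0.05 in 35. Figures were drawn with matplotlib 3.10.9.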

Results

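Gnotobiotic mice, which carry only the bacteria given to them, were colonized with 1 of 3 defined communities of human gut bacteria. The study examined how the make-up of the community, the host's strain and sex, and the diet bear on the build-up of trimethylamine-N-oxide, a compound made in the host from trimethylamine that gut bacteria release from choline. The data hold 116 libraries from 34 mice. Each library gives the relative abundance of 13 species and the total number of raw reads.

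The core community had 5 species. Bacteroides caccae, Bacteroides ovatus and Bacteroides thetaiotaomicron are Bacteroidetes that degrade plant and host glycans, Collinsella aerofaciens is a saccharolytic member of the Actinobacteria, and Eubacterium rectale is a butyrate-forming Firmicute. The 6-species community added Clostridium sporogenes, an anaerobic Firmicute. The 13-species community held 8 species beyond the core, all of them species known to form trimethylamine from choline. They were C. sporogenes, 3 other Firmicutes (Anaerococcus hydrogenalis, Clostridium asparagiforme and Clostridium hathewayi) and 4 Proteobacteria (Edwardsiella tarda, Escherichia fergusonii, Proteus penneri and Providencia rettgeri).

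Set 1 compared the communities in male C57BL/6J mice, an inbred strain, on the choline-plus diet. It had 4 mice with 5 species, 5 with 6 species and 5 with 13 species, each sampled at the proximal small intestine, distal small intestine, cecum and distal large intestine. Set 2 held 20 mice with the 13-species community at the last 3 of these sites. These were C57BL/6J males on the choline-plus (3 mice) and choline-minus diet (3 mice), and mice of the outbred NMRI stock, namely 4 males on choline plus, 5 males on choline minus and 5 females on choline plus.

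Depth differed by site. Cecal libraries of set 1 held 9680 to 432854 reads (14 libraries) and those of set 2 held 10303 to 292964 (20 libraries). Distal large-intestinal libraries held 6101 to 338478 reads in set 1. In set 2 they reached 296168, and 1 library, from mouse 2 of the C57BL/6J choline-minus group, held 26. Distal small-intestinal libraries held 53 to 63485 reads in set 1. In set 2 the 6 C57BL/6J mice gave 1428 to 20705 reads at that site, while 13 of the 14 NMRI libraries held fewer than 50. Proximal small-intestinal libraries, from set 1 alone, held 41 to 3660 reads. In all, 92 libraries held at least 1000 reads.

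**Figure D1:**
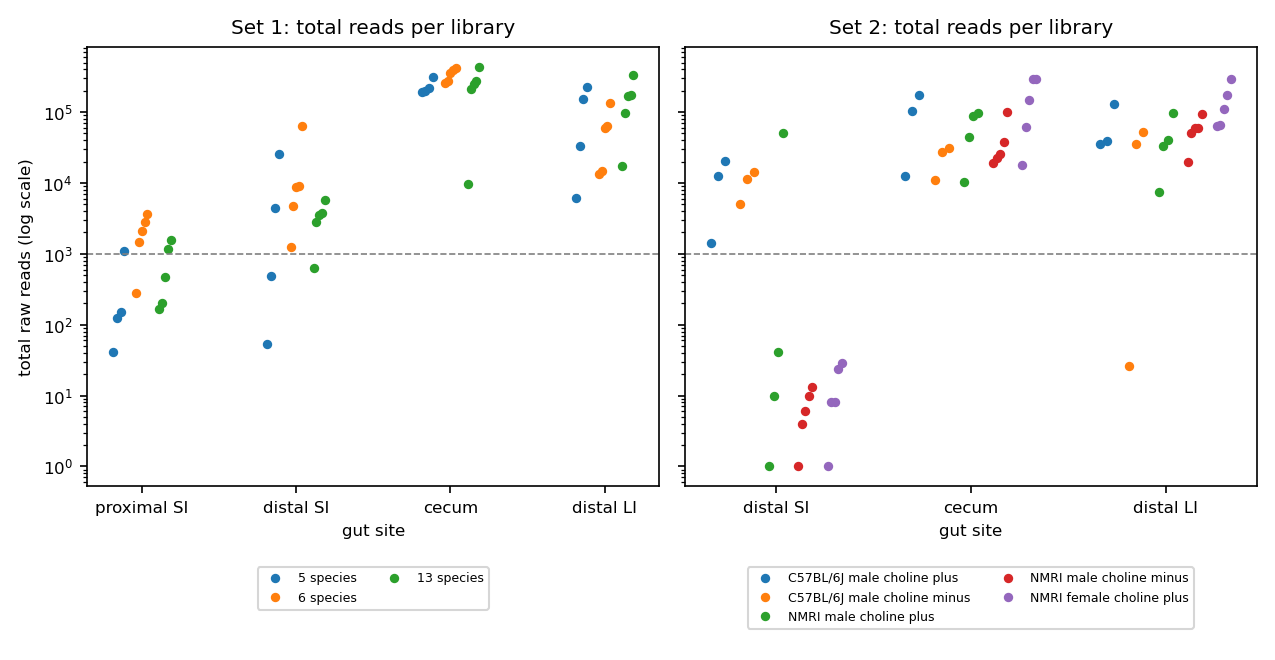
Total raw reads per library (log scale) by gut site in set 1 and set 2, 1 point per library, colored by group, with the dashed line at 1000 reads (SI, small intestine; LI, large intestine). All 34 cecal libraries lie above the line, and 13 of the 14 NMRI distal small-intestinal libraries hold fewer than 50 reads.

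In the 13-species mice of set 1 the 3 Bacteroides species made up most of the cecal community, with 72.1% ± 1.93 (SD, n = 5). B. caccae took 34.9% ± 2.79, B. thetaiotaomicron 23.1% ± 1.63 and B. ovatus 14.0% ± 1.16 (SD, n = 5 each). The 8 added species together took 23.2% ± 2.16 (SD, n = 5), of which the 4 Proteobacteria were 13.2% ± 1.35. C. hathewayi (5.06% ± 0.897), E. tarda (4.86% ± 0.826), C. asparagiforme (4.84% ± 1.76) and E. fergusonii (4.74% ± 0.982) had similar means, followed by C. aerofaciens (4.48% ± 0.569), P. rettgeri (2.00% ± 0.209) and P. penneri (1.58% ± 0.187). E. rectale had 0.238% ± 0.0329, C. sporogenes 0.124% ± 0.0551 and A. hydrogenalis 0.00933% ± 0.00974 (SD, n = 5 each; A. hydrogenalis 0.00527% without mouse 1). The Firmicutes summed to 10.3% ± 1.13.

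The first question was whether the 5 core species keep their proportions to each other when species are added, so their shares of the core were compared. With C. sporogenes added, C. aerofaciens rose in the cecum from 6.02% ± 1.39 of the core in 5-species mice (SD, n = 4) to 11.1% ± 1.96 in 6-species mice (SD, n = 5). All 5 of the 6-species mice lay above the 5-species mean (log2 difference 0.89, SE 0.16, limma adjusted p 0.00295). It was the 1 call among 20 tests of 5 species at 4 sites, with 2 tests at an unadjusted p under 0.05. In the cecum the other 4 core species had adjusted p of at least 0.616. B. caccae took 46.7% ± 5.91 of the core in 5-species and 43.9% ± 8.21 in 6-species mice, and E. rectale 0.915% ± 0.314 and 0.748% ± 0.420. The call for C. aerofaciens held without any 1 of the 9 mice, with log2 differences between 0.80 and 1.03. On centred log-ratios the difference was 0.99 but the call was not made (adjusted p 0.0876). Over the alternatives other than leaving out mice the difference lay between 0.88 and 0.99 (adjusted p 0.000739 to 0.159). The core composition of the cecum as a whole gave an R2 of 0.173 (share of the squared Bray-Curtis distances between mice that the groups explain, one-sided exact permutation test, p 0.198, n = 5 and 4), and without 6-species mouse 5 it gave 0.359 (p 0.0286).

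With all 8 species added, limma called 0 of 20 tests of the core against the 5-species mice, with 1 at an unadjusted p under 0.05. In the cecum C. aerofaciens took 5.82% ± 0.658 of the core (SD, n = 5) against 6.02% ± 1.39 (SD, n = 4), a log2 difference of -0.03 (95% interval -0.38 to 0.33). B. ovatus took 18.3% ± 1.76 against 14.6% ± 1.08, B. thetaiotaomicron 30.1% ± 2.11 against 31.8% ± 4.95, and E. rectale 0.312% ± 0.0517 against 0.915% ± 0.314, below the 5-species mean in 5 of 5 mice (log2 difference -1.47, SE 1.12, adjusted p 0.789). The spread of that fit includes 6-species mouse 4, in which E. rectale made up 0.00111% of the cecal reads. With only the 2 groups compared in the fit, E. rectale was the 1 call (-1.47, SE 0.20, adjusted p 0.000151). The count was also 1 when shares of the whole community were used: there B. thetaiotaomicron had 23.1% ± 1.63 in 13-species against 31.8% ± 4.95 in 5-species mice (log2 difference -0.45, adjusted p 0.0424). The cecal R2 of the core was 0.200 (exact permutation test, p 0.222, n = 5 and 4), 0.345 on square-root shares (p 0.0317) and 0.764 on Aitchison distances, which weigh scarce species as much as abundant ones (p 0.00794).

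Against the 6-species mice, the 13-species mice had less C. aerofaciens in the cecal core. It fell by 0.91 on the log2 scale (SE 0.15, limma adjusted p 0.00131) from 11.1% ± 1.96 to 5.82% ± 0.658 of the core (SD, n = 5 each), and all 5 of the 13-species mice lay below the 6-species mean. In the distal small intestine the same species took 11.9% ± 9.38 of the core in 13-species and 35.3% ± 13.8 in 6-species mice (log2 difference -1.84, adjusted p 0.109). The cecal call was the 1 call of 20 tests, with 3 at an unadjusted p under 0.05. It was not made on centred log-ratios, where the difference was -0.76 (adjusted p 0.149), and over the alternatives other than leaving out mice the difference lay between -1.29 and -0.76 (adjusted p 5.05e-05 to 0.149). Leaving out 6-species mouse 4, in which E. rectale made up 0.00111% of the cecal reads, gave 8 calls, and leaving out 13-species mouse 2 gave 2. The cecal R2 of the core was 0.229 (exact permutation test, p 0.111, n = 5 each), and it was 0.410 without 6-species mouse 4 (p 0.00794) and 0.426 without 6-species mouse 5 (p 0.00794).

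**Figure D2:**
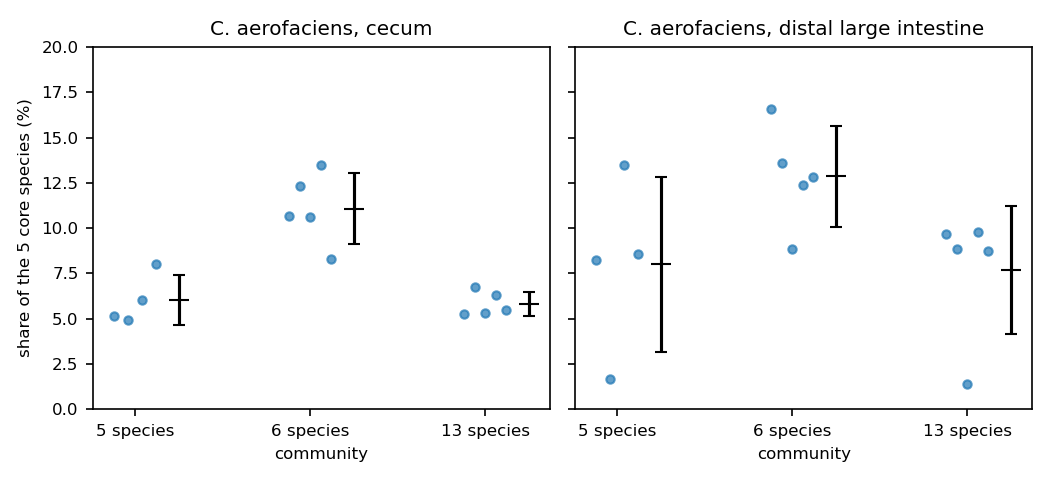
Share of the 5 core species held by C. aerofaciens (percent) in the cecum and the distal large intestine of set 1, 1 point per mouse, with bars for the mean and SD (n = 4, 5 and 5). The cecal means are 6.02% (5 species), 11.1% (6 species) and 5.82% (13 species).

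C. sporogenes, the 1 species that the 6-species community held beyond the core, took a similar cecal share with and without the 7 other added species. It had 0.129% ± 0.0359 of the reads in 6-species mice and 0.124% ± 0.0551 in 13-species mice (SD, n = 5 each). The log2 difference was -0.09 (SE 0.28, 95% interval -0.71 to 0.53, limma, unadjusted p 0.742 as the single planned test). Its sign turned without 13-species mouse 4 (0.01) and without 6-species mouse 4 (0.004), and on centred log-ratios (0.37) and as a ratio to the core (0.29). In the 5-species mice, which had not been given it, C. sporogenes was listed at 0 in all 16 libraries, which together allow a share of up to 0.000219%.

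Along the gut of the 6-species mice, C. aerofaciens rose from 11.1% ± 1.96 of the reads in the cecum to 34.9% ± 13.3 in the distal small intestine (SD, n = 5 each), and B. caccae fell from 43.9% ± 8.19 to 27.9% ± 5.05. B. thetaiotaomicron fell from 28.9% ± 3.19 to 20.4% ± 5.83. Each of the 3 moved the same way in 5 of 5 mice, with log2 differences of 1.59 (SE 0.32, limma adjusted p 0.0027), -0.65 (SE 0.13, adjusted p 0.0027) and -0.55 (SE 0.14, adjusted p 0.00881). These were the 3 calls of 18 tests, and the call for B. thetaiotaomicron ended without mouse 1 (adjusted p 0.0711) and without mouse 2 (adjusted p 0.0802). C. sporogenes had 0.307% ± 0.198 in the distal small intestine (n = 5) and was not called.

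In the 5-species mice limma called 0 of 15 tests of site, with 0 at an unadjusted p under 0.05, and 1 test without mouse 2. C. aerofaciens there took 17.2% ± 10.5 of the distal small-intestinal and 6.02% ± 1.39 of the cecal reads (SD, n = 4 each). In the 13-species mice of set 1 limma called 0 of 39 tests, with 2 at an unadjusted p under 0.05. One of these was E. tarda, with 7.71% ± 2.21 in the distal small intestine and 4.86% ± 0.826 in the cecum (SD, n = 5 each), higher in 5 of 5 mice (log2 difference 0.64, adjusted p 0.325). C. sporogenes had 0.174% ± 0.123 and 0.124% ± 0.0551 at the same sites.

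In set 2 the 6 C57BL/6J mice, all with at least 1000 reads at both sites, had 41.7% ± 10.8 Proteobacteria in the distal small intestine and 13.4% ± 2.85 in the cecum (SD, n = 6 each). E. tarda had 16.8% ± 9.56 against 3.58% ± 1.87, E. fergusonii 18.2% ± 8.81 against 6.57% ± 1.98 and C. sporogenes 0.546% ± 0.178 against 0.244% ± 0.101. The Bacteroidetes had 40.6% ± 12.4 against 70.7% ± 4.15. In a fit over all libraries of set 2 of at least 1000 reads, limma called 11 species in the distal small intestine. There 7 mice, 1 of them an NMRI male, had libraries at both sites. The spread behind the SE and p is pooled over 7 distal small-intestinal, 20 cecal and 19 distal large-intestinal libraries. It does not measure the spread of the distal small-intestinal difference among the 7 mice alone. E. tarda rose (log2 difference 1.82, SE 0.26, adjusted p 2.07e-06, 7 of 7 mice), as did C. sporogenes (1.00, SE 0.36, adjusted p 0.026, 7 of 7), while C. hathewayi fell by 1.00 (SE 0.20, adjusted p 0.000217, 7 of 7). E. fergusonii was called higher (1.02, adjusted p 0.00167, 5 of 7) and C. asparagiforme lower (-0.92, adjusted p 0.0017, 6 of 7). Of the 6 other calls 3 were higher (0.65 to 0.87) and 3 lower (-0.81 to -0.59). The higher ones include A. hydrogenalis, which was near the floor. It was listed at 0.158% of 1428 reads in C57BL/6J choline-plus mouse 2 and 0.0501% of 5029 reads in choline-minus mouse 3. Both are less than the share of 3 reads, and the other mice list it at 0 there. P. penneri was the 1 call in the distal large intestine (0.39, adjusted p 0.0493, 14 of 19 mice). This restriction on depth was chosen after the data were seen. With all 20 mice, of which 13 had fewer than 50 distal small-intestinal reads, limma called 8 species, all lower in the distal small intestine, C. sporogenes (-1.83) and C. aerofaciens (-3.73) among them.

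The diet comparison asked whether choline in the diet changes the 13-species community. In the cecum of C57BL/6J males, C. asparagiforme had 4.00% ± 0.802 on choline minus and 6.16% ± 1.62 on choline plus (SD, n = 3 each), and E. tarda had 4.92% ± 1.57 and 2.25% ± 0.944. Neither was called: limma called 0 of 37 tests over 3 sites, with 2 at an unadjusted p under 0.05 (P. penneri and P. rettgeri in the distal large intestine). C. sporogenes had 0.244% ± 0.131 and 0.244% ± 0.0906 in the cecum. The cecal sums were 24.7% ± 3.79 and 24.1% ± 3.16 for the 8 added species, 71.1% ± 4.37 and 70.3% ± 4.84 for Bacteroidetes, 9.34% ± 1.19 and 12.7% ± 1.71 for Firmicutes, and 15.3% ± 2.62 and 11.4% ± 1.46 for Proteobacteria, with 0 of 12 tests of sums called by limma (0 at an unadjusted p under 0.05). Without mouse 2 of the choline-minus group, whose distal large-intestinal library held 26 reads, limma called 2 species in the distal large intestine, C. asparagiforme (-1.04, adjusted p 0.0292, 2 of 2 mice) and C. hathewayi (-0.70, adjusted p 0.0217, 2 of 2), and the Firmicutes sum (-0.82, adjusted p 0.00245, 2 of 2). The cecal R2 was 0.333 (exact permutation test, p 0.1, the smallest that 3 against 3 mice can give).

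In NMRI males C. asparagiforme was lower on choline minus, and by more than the spread between mice. In the cecum it fell by 1.60 on the log2 scale (SE 0.32, limma adjusted p 0.00192), to 2.17% ± 0.480 (SD, n = 5) from 6.51% ± 0.692 (SD, n = 4). In the distal large intestine it fell by 2.10 (SE 0.33, adjusted p 0.000287), to 1.71% ± 0.316 from 7.57% ± 2.77. All 5 choline-minus mice lay below the choline-plus mean at both sites, and both calls held without any 1 of the 9 mice. P. penneri fell in the cecum by 1.21 (SE 0.33, adjusted p 0.0225), to 0.601% ± 0.181 from 1.38% ± 0.301, in 5 of 5 mice. These were the 3 calls of 37 tests, with 5 at an unadjusted p under 0.05. E. tarda had 5.30% ± 2.12 on choline minus and 2.24% ± 1.20 on choline plus in the cecum (adjusted p 0.162). The call for P. penneri ended without choline-minus mouse 4 (adjusted p 0.0728) or choline-plus mouse 2 (0.0779), 3 (0.0801) or 4 (0.0561).

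No other species in NMRI males was called between the diets in the main fit. In libraries of at least 1000 reads limma also called C. aerofaciens lower on choline minus in the distal large intestine (-0.52, adjusted p 0.0416). That call was also made in 2 of 9 fits with 1 mouse left out. C. sporogenes had 0.290% ± 0.333 on choline minus (SD, n = 5) and 0.122% ± 0.0677 on choline plus (SD, n = 4) in the cecum (log2 difference 0.64, SE 0.77), and 0.152% on choline minus without mouse 2, which had 0.842%. In the distal large intestine the Firmicutes had 6.96% ± 0.677 and 12.6% ± 2.89 (log2 difference -0.83, limma adjusted p 0.0596, lower in 5 of 5 mice; 4.95e-05 in libraries of at least 1000 reads, and up to 0.998 over all alternatives), the 8 added species 15.3% ± 3.12 and 20.6% ± 3.69, the Bacteroidetes 80.8% ± 3.65 and 73.9% ± 4.23, and the Proteobacteria 8.36% ± 2.93 and 7.98% ± 1.88. For the Firmicutes, the restriction to 1000 reads drops none of the libraries compared. It takes a C57BL/6J choline-minus library of 26 reads out of the spread of the fit, and the distal small-intestinal tests out of the adjustment. limma called 0 of 12 tests of sums, with 2 at an unadjusted p under 0.05, and it called 2 without choline-plus mouse 1, 2 without choline-plus mouse 4 and 1 without choline-minus mouse 1. The whole cecal community gave an R2 of 0.322 (exact permutation test, p 0.0159, n = 5 and 4; 0.0716 adjusted over the 8 cecal tests). That p was above 0.05 without choline-minus mouse 1 (0.114) or 5 (0.0571), or choline-plus mouse 1 (0.0536), 2 (0.0714) or 4 (0.0536).

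Whether the diet difference itself differed between the strains was tested as an interaction. limma called 0 of 37 species tests, with 3 at an unadjusted p under 0.05, and 0 of 12 tests of sums, with 1. The C. asparagiforme interaction was -0.99 in the cecum (SE 0.51, adjusted p 0.48) and -1.70 in the distal large intestine (SE 0.52, adjusted p 0.164), and that of C. sporogenes in the cecum was 0.71 (SE 1.22). C. hathewayi, singled out after its values were seen, had 0.26 in the distal large intestine (adjusted p 0.802), and 0.78 (SE 0.20, adjusted p 0.0402) in libraries of at least 1000 reads, where 2 C57BL/6J choline-minus mice remained. Without C57BL/6J choline-minus mouse 3 the count was 1.

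The strain comparison asked whether the host's genetic background changes the community. P. rettgeri was lower in the cecum of NMRI than of C57BL/6J males on both diets. On choline plus it stood at 0.363% ± 0.201 of the cecal reads in NMRI males (SD, n = 4) against 2.38% ± 0.224 in C57BL/6J males (SD, n = 3), a log2 difference of -2.83 (SE 0.44, limma adjusted p 0.00022), lower in 4 of 4 mice. On choline minus it stood at 0.282% ± 0.0464 (SD, n = 5) against 1.43% ± 0.125 (SD, n = 3), a log2 difference of -2.31 (SE 0.42, adjusted p 0.00145), lower in 5 of 5 mice. Both calls held without any 1 of the mice compared. In the distal large intestine it had 0.273% ± 0.193 against 2.28% ± 0.0637 on choline plus (log2 difference -3.22, adjusted p 0.152), and 0.178% in NMRI males without mouse 3. The adjusted p there was 6.9e-06 in libraries of at least 1000 reads. That restriction drops none of the libraries compared here. It takes a C57BL/6J choline-minus library of 26 reads out of the spread of the fit, and the distal small-intestinal tests out of the adjustment. In the distal large intestine on choline minus P. rettgeri had 0.276% ± 0.0889 against 0.872% ± 0.794 (0.532% without C57BL/6J mouse 3), and the log2 difference was 0.11 (adjusted p 1). C57BL/6J mouse 2, with 26 reads, lists it at 0 there, and the other 2 mice at 1.06% and 1.55%. Without mouse 2 the difference was -2.23 (adjusted p 0.00253).

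On choline plus, the other call was B. thetaiotaomicron in the distal large intestine, with 26.7% ± 1.66 in NMRI (SD, n = 4) and 20.7% ± 1.70 in C57BL/6J males (SD, n = 3), a log2 difference of 0.37 (SE 0.10, limma adjusted p 0.0456, higher in 4 of 4 mice). It made 2 calls of 37 tests, with 6 at an unadjusted p under 0.05. The call ended, leaving 1, without NMRI mouse 1 (adjusted p 0.145), 3 (0.0931) or 4 (0.112) or C57BL/6J mouse 1 (0.117) or 2 (0.269). C. sporogenes had 0.122% ± 0.0677 and 0.244% ± 0.0906 in the cecum. The cecal sums were 19.0% ± 3.37 and 24.1% ± 3.16 for the 8 added species, 77.3% ± 4.47 and 70.3% ± 4.84 for Bacteroidetes, 11.6% ± 1.46 and 12.7% ± 1.71 for Firmicutes and 7.33% ± 2.03 and 11.4% ± 1.46 for Proteobacteria, with 0 of 12 tests called by limma and 1 at an unadjusted p under 0.05. The cecal R2 was 0.380 (exact permutation test, p 0.114, n = 4 and 3).

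On choline minus, limma called 8 of 37 tests, 7 of them lower in NMRI males, with 12 at an unadjusted p under 0.05. E. fergusonii was lower in the cecum, with 3.02% ± 0.994 (SD, n = 5) against 7.90% ± 0.935 (SD, n = 3; log2 difference -1.44, SE 0.40, adjusted p 0.0123, 5 of 5 mice), and in the distal large intestine, with 2.33% ± 0.419 against 5.99% ± 2.03 (-1.33, SE 0.34, adjusted p 0.00951, 5 of 5 mice). Also in the distal large intestine, B. thetaiotaomicron was higher, with 27.9% ± 1.58 against 20.1% ± 0.143 (0.47, SE 0.10, adjusted p 0.00356, 5 of 5 mice). C. aerofaciens was lower there, with 3.83% ± 0.635 against 7.00% ± 1.71 (-0.85, SE 0.20, adjusted p 0.00674, 5 of 5 mice), and so was C. asparagiforme, with 1.71% ± 0.316 against 4.98% ± 4.16 (-1.25, SE 0.36, adjusted p 0.0151, 5 of 5 mice). The remaining calls, C. hathewayi and C. aerofaciens in the distal small intestine, rest on NMRI libraries of at most 13 reads that list both at 0, and 3 reads make up at least 23.1% of such a library. C. sporogenes had 0.290% ± 0.333 (0.152% without NMRI mouse 2) and 0.244% ± 0.131 in the cecum. Without C57BL/6J mouse 3 the count was 5, and E. fergusonii had adjusted p of 0.0573 in the cecum and 0.0688 in the distal large intestine. Without C57BL/6J mouse 2 (26 reads in the distal large intestine) C. asparagiforme stood at -0.61 (adjusted p 0.0828), with a C57BL/6J mean of 2.58%. C. hathewayi at that site, at 0.16 in the main fit, was called higher in NMRI males in libraries of at least 1000 reads (0.68, limma adjusted p 0.00293).

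For the group sums on choline minus, NMRI males had less of the 8 added species in the distal large intestine, with 15.3% ± 3.12 (SD, n = 5) against 25.7% ± 5.41 in C57BL/6J males (SD, n = 3; log2 difference -0.74, SE 0.18, limma adjusted p 0.00928). The Bacteroidetes were higher, with 80.8% ± 3.65 against 67.3% ± 6.96 (0.27, SE 0.08, adjusted p 0.0257), and the Proteobacteria lower, with 8.36% ± 2.93 against 15.3% ± 6.39 (-0.85, SE 0.29, adjusted p 0.0381), each in 5 of 5 mice. The Firmicutes had 6.96% ± 0.677 against 10.4% ± 7.50 (log2 difference -0.36, adjusted p 0.329). That C57BL/6J mean rests on mouse 2 (19.1% of 26 reads): without it the mean was 6.06% and the difference turned to 0.19 in libraries of at least 1000 reads (adjusted p 0.313). These 3 calls of 12 became 1 without NMRI mouse 4, 1 without NMRI mouse 5 and 0 without C57BL/6J mouse 3. The Bacteroidetes call also ended without C57BL/6J mouse 2 (adjusted p 0.0771), and the Proteobacteria call without NMRI mouse 3 (0.0771) or C57BL/6J mouse 1 (0.0686). The cecal R2 was 0.449 (exact permutation test, p 0.0179, the smallest that 5 against 3 mice can give; 0.0716 adjusted over 8), and 0.367 without C57BL/6J mouse 1 (p 0.0952).

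The sex comparison asked whether NMRI females and males on choline plus differ. P. penneri was lower in females in the cecum, with 0.542% ± 0.228 (SD, n = 5) against 1.38% ± 0.301 in males (SD, n = 4; log2 difference -1.44, SE 0.33, limma adjusted p 0.0143), and P. rettgeri likewise, with 0.163% ± 0.110 against 0.363% ± 0.201 (-1.19, SE 0.39, adjusted p 0.0438). C. hathewayi was higher in the cecum of females, with 8.36% ± 0.746 against 5.01% ± 1.28 (0.77, SE 0.22, adjusted p 0.032), and so was C. aerofaciens, with 8.44% ± 5.64 against 3.69% ± 1.27 (1.07, SE 0.34, adjusted p 0.0438). In the distal large intestine C. asparagiforme was lower in females, with 3.17% ± 0.509 against 7.57% ± 2.77 (-1.20, SE 0.33, adjusted p 0.032). Each of these held in 5 of 5 females relative to the male mean. They were 5 of the 6 calls of 37 tests, with 10 at an unadjusted p under 0.05. The other was P. rettgeri in the distal small intestine, where the females' libraries of at most 29 reads list it at 0. The male mean there, 32.6%, rests on a library of 1 read (mouse 4, 100%) and is 10.2% without it. C. sporogenes had 0.444% ± 0.611 in females and 0.122% ± 0.0677 in males in the cecum (adjusted p 0.428), and 0.173% ± 0.0944 in females without mouse 1, which had 1.53%.

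The count of 6 became 1 without female mouse 5, 2 without male mouse 2 and 3 without male mouse 4, which left P. penneri as the 1 cecal call that held without any 1 of the 9 mice. Beyond those mice, the call for C. aerofaciens ended without female mouse 1 (log2 difference 0.74) or male mouse 1 (0.88), and that for P. rettgeri in the cecum without female mouse 1 (-0.86), female mouse 2 (-1.16) or male mouse 3 (-0.88). The cecal sums were 27.1% ± 10.1 in females (SD, n = 5) and 19.0% ± 3.37 in males (SD, n = 4) for the 8 added species, 64.5% ± 15.7 and 77.3% ± 4.47 for Bacteroidetes, 14.0% ± 4.00 and 11.6% ± 1.46 for Firmicutes, and 13.1% ± 6.40 and 7.33% ± 2.03 for Proteobacteria. limma called 0 of 12 tests of sums, with 1 at an unadjusted p under 0.05. The cecal R2 was 0.261 (exact permutation test, p 0.0397, n = 5 and 4; 0.106 adjusted over 8), and its p was above 0.05 without female mouse 5 (0.0571) or male mouse 1 (0.196), 2 (0.25), 3 (0.0893) or 4 (0.196). The diet comparison in NMRI males, the strain comparison on choline plus and the sex comparison share the 4 NMRI males on choline plus.

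**Figure D3:**
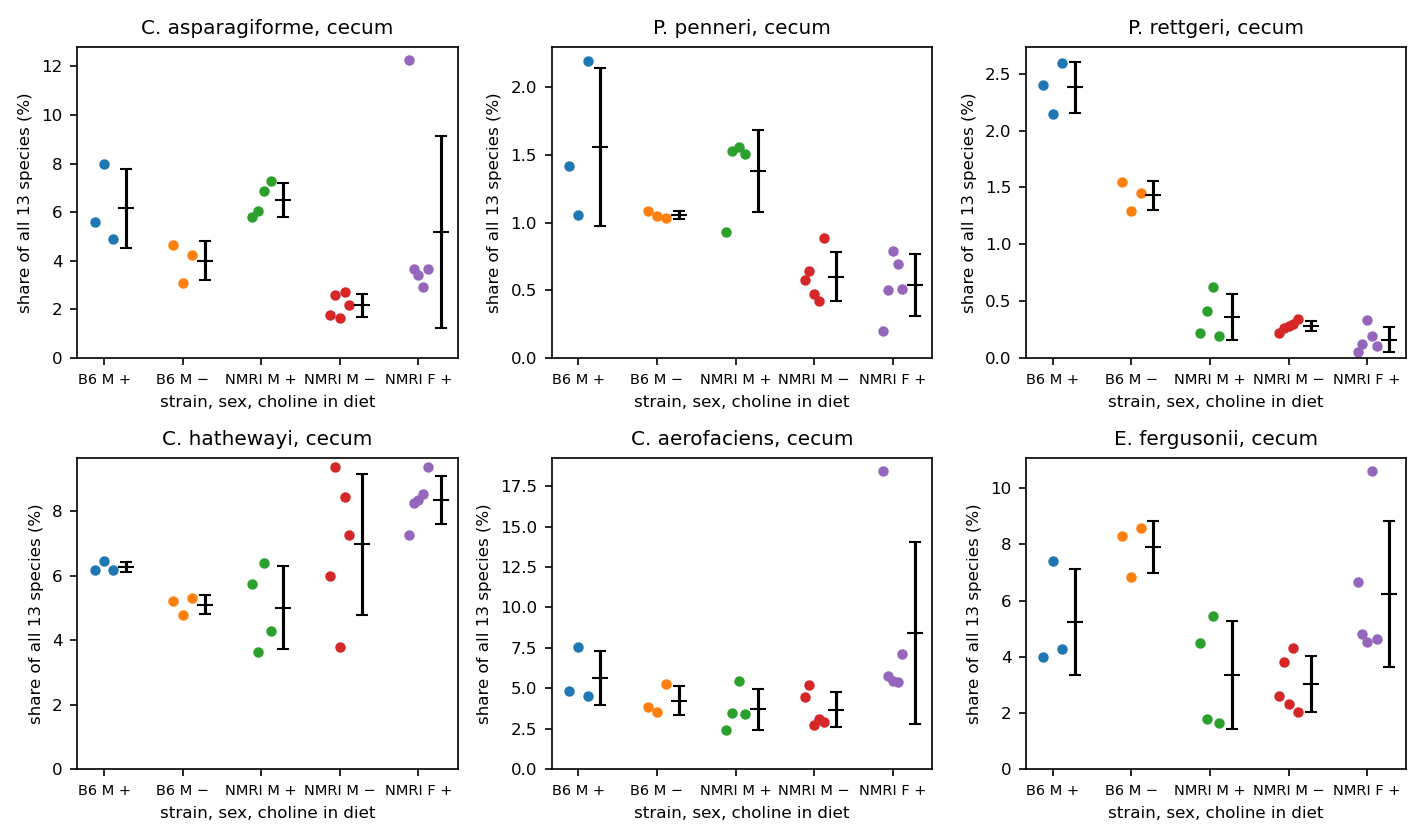
Cecal shares (percent of all 13 species) of 6 species in the 5 groups of set 2, 1 point per mouse, with bars for the mean and SD (n = 3, 3, 4, 5 and 5 from left to right; B6, C57BL/6J; M, male; F, female; + and −, choline plus and minus). P. rettgeri lies at 2.38% and 1.43% in the C57BL/6J groups and at 0.363%, 0.282% and 0.163% in the NMRI groups.

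Species that a mouse had not been given served as the background of the species assignment. In the cecum of 5- and 6-species mice other than 6-species mouse 5 they summed to at most 0.00106% of the reads (8 libraries). In the distal large intestine the highest sum in those mice was 0.0204%, in the distal small intestine 5.09% and in the proximal small intestine 8.54% (8 libraries each). These last 2 come from libraries of 53 and 41 reads. The next highest were 1.17% and 3.71%, and the medians 0.0794% and 0.812%. In 6-species mouse 5 they summed to 0.0859% in the cecum (95% Wilson interval 0.0753% to 0.0980%), 0.503% in the distal large intestine, 2.10% in the distal small intestine and 19.6% in the proximal small intestine.

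**Figure D4:**
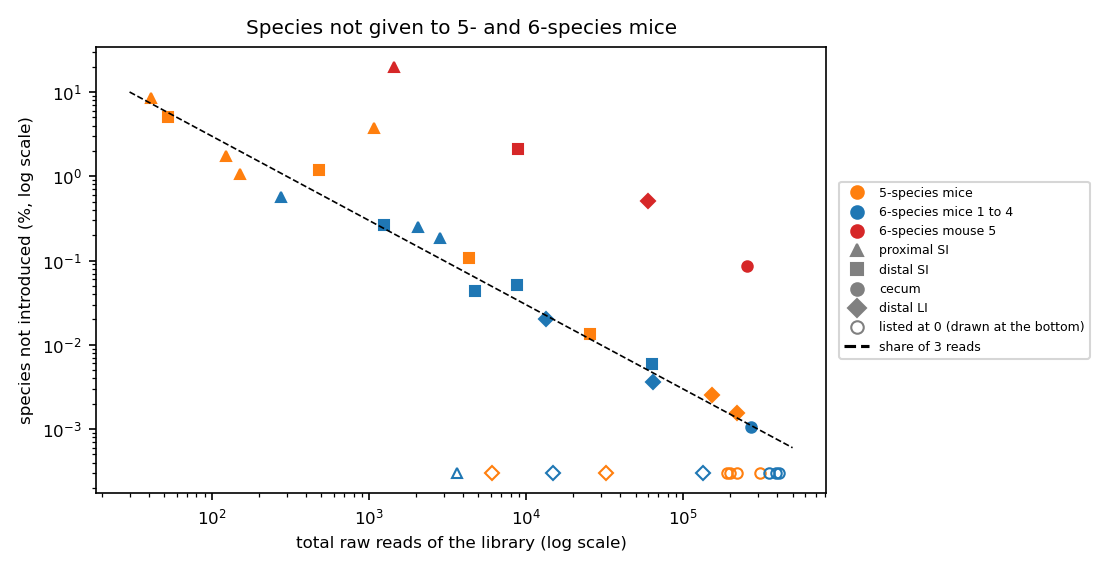
Summed share of species not given to the mouse (percent, log scale) against the library's total raw reads (log scale) in the 36 libraries of 5- and 6-species mice. The dashed line is the share that 3 reads make up. Above it lie 16 of the 36 libraries, among them all 4 of 6-species mouse 5 and the proximal small-intestinal library of 5-species mouse 4 (3.71%, 7 species).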

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

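The tests of the patterns in 6-species mouse 5, in E. rectale and in the depth of NMRI libraries were chosen only after those patterns were seen, and the counts of other splits of the mice were planned.

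In 6-species mouse 5, species not given to it were listed at every gut site. Of the 7 such species, 6 were listed in the cecum and in the distal large intestine, and all 7 in the distal and proximal small intestine. They summed to 0.0859% of the reads in the cecum, 0.503% in the distal large intestine, 2.10% in the distal small intestine and 19.6% in the proximal small intestine. Each sum was above the limit that 3 reads set. Stable colonization in the proportions of 13-species mice is argued against, because the share in the proximal small intestine was 228.8 times that in the cecum, while the same ratio lay between 0.925 and 1.20 in the 13-species mice. The share times the library's total varied by 1.608-fold over the 4 libraries, from 188.8 to 303.6, although the totals varied by 178.2-fold. For normalized shares this product is only an approximate number of reads. Carried-over DNA or reads of 13-species samples could give such a near-constant product. A mislabelled 13-species sample stays open for the proximal small-intestinal library alone: the 8 added species made up 19.99% of it (95% Wilson interval 18.0% to 22.1%), and the 13-species libraries of that site ranged from 20.8% to 32.2%.

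E. rectale was listed above 0 in 1 of the 60 libraries of set 2, a cecal C57BL/6J choline-plus library of 12336 reads with 0.0126%. Too few reads are argued against, since 3 reads allow at most 0.02912% in any cecal library of set 2 and the lowest cecal share in the 13-species mice of set 1 was 0.208%. A species list without E. rectale is argued against by the 1 library that lists it. A lower level or failed colonization in the mice of set 2 and a difference between the 2 tables in read assignment remain open and were not tested.

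In NMRI mice 13 of the 14 distal small-intestinal libraries held fewer than 50 reads, and the median total there was 0.000759 times that of the C57BL/6J mice. Shallower sequencing of NMRI libraries at every site is argued against, because their median total was 1.842 times that of C57BL/6J mice in the cecum and 1.67 times in the distal large intestine. Fewer bacteria in the sampled segment, more host DNA and a failed batch of libraries of that site remain open, as untested.

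Other 5- and 6-species libraries also listed species not given to the mouse above the 3-read limit. In the 5-species mice these were the distal large intestine of mouse 1 (0.00256%) and mouse 3 (0.00156%), the distal small intestine of mouse 1 (0.0135%), mouse 3 (1.17%) and mouse 4 (0.108%), and the proximal small intestine of mouse 2 (8.54%) and mouse 4 (3.71%, with 7 species listed, about 40.3 reads). In the 6-species mice they were the distal small intestine of mouse 1 (0.00589%), mouse 2 (0.0508%) and mouse 3 (0.264%) and the proximal small intestine of mouse 2 (0.2501%) and mouse 4 (0.188%). In all, 16 of the 36 libraries were above the limit, those of 6-species mouse 5 included.

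Single mice lay far from the rest of their group, by the gap to the nearest mouse relative to the range, in 30 of 154 tests of a species or sum in a group, over 12 groups of mice and sites. Chance gives about 5% of such tests for independent and normally distributed values. The features of a library are not independent, since shares add up to 1 and the sums repeat the species. The 30 of 154 lie above that 5%, but because of this dependence the count was not judged against chance. NMRI female mouse 1 stood apart in the cecum in 10 features, with 18.4% C. aerofaciens, 17.0% E. tarda, 12.2% C. asparagiforme, 1.53% C. sporogenes, 45.0% of the 8 added species and 21.1% Firmicutes as the highest values, and 16.8% B. caccae, 14.7% B. thetaiotaomicron, 5.12% B. ovatus and 36.6% Bacteroidetes as the lowest. In 13-species mouse 3 of set 1 the distal large intestine had 47.9% B. thetaiotaomicron and 86.5% Bacteroidetes, with 1.22% C. aerofaciens, 0.465% P. rettgeri and 3.34% Firmicutes. Mouse 1 of that group had 6.31% E. tarda at the same site. In the cecum, mouse 5 of that group had 7.95% C. asparagiforme, 0.221% C. sporogenes, 27.0% of the 8 added species and 68.7% Bacteroidetes.

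Further single values apart from their group were as follows. In the cecum 6-species mouse 4 had 22.7% B. ovatus, 0.00111% E. rectale and 0.169% Firmicutes, and 6-species mouse 5 had 23.4% B. thetaiotaomicron. The distal large intestine of 5-species mouse 2 held 56.7% B. thetaiotaomicron. Among NMRI females, mouse 4 had 8.84% E. fergusonii and mouse 5 had 11.5% Firmicutes in the distal large intestine. NMRI choline-minus male mouse 1 had 10.1% E. tarda in the distal large intestine, NMRI choline-plus male mouse 1 had 0.932% P. penneri in the cecum, and mouse 3 of that group had 0.561% P. rettgeri in the distal large intestine.

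The diet difference of C. hathewayi in the distal large intestine differed between NMRI and C57BL/6J males in libraries of at least 1000 reads, by 0.78 on the log2 scale (limma adjusted p 0.0402), and that fit leaves 2 C57BL/6J choline-minus mice.

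For chance as the source of the counts of calls, other splits of the mice into groups of the same sizes were fitted. The share of splits that reached the real count was under 0.05 for strain on choline minus. There the real 8 calls were reached by 1 of 56 splits, the real one itself, with 2 calls in the highest other split. It was also under 0.05 for strain on choline plus (2 calls, 1 of 35 splits, highest other 1), for sex (6 calls, 1 of 100 splits, highest other 3) and for the 6- against the 5-species core (1 call, 4 of 100 splits, highest other 3). These shares were not adjusted over the comparisons, so they argue against chance without excluding it. The counts for strain on choline minus and sex include distal small-intestinal calls resting on NMRI libraries of at most 13 and 29 reads. Such splits cannot tell a group from an isolator that its mice share. For site the share was also under 0.05 in set 2 (8 calls, 1 of 100 splits, highest other 7) and in the 6-species mice (3 calls, 3 of 100 splits, highest other 9). The 8 calls of set 2, all lower in the distal small intestine, come from a fit with 13 libraries under 50 reads there. Shuffled site labels carry depth along with site, so these splits cannot tell a site difference from low depth. In libraries of at least 1000 reads that fit gave 12 calls, 7 of them higher. A split with 9 calls points to a structure of the samples. Gut site itself can be that structure, since a split may put the distal small-intestinal libraries in the place of the cecal ones, and the cause was not tested. The share was 0.05 or more, which leaves chance open, for diet in NMRI males (3 calls, 5 of 100 splits, highest other 4), for the 13- against the 6-species core (1 call, 6 of 100 splits, highest other 3), and for the sums on choline minus between the strains (3 calls, 3 of 56 splits, highest other 3).

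Where the real count was 0 every split reached it. This was so for the 13- against the 5-species core (100 of 100 splits, highest other 2), the sums by diet in NMRI males (100 of 100, highest other 2), the sums by sex (100 of 100, highest other 1), the sums by strain on choline plus (35 of 35, highest other 0), the interaction for species and for sums (100 of 100 each, highest other 1 each), and site in the 5-species and the 13-species mice of set 1 (100 of 100 each, highest other 3 each). For diet in C57BL/6J males there are 10 splits, too few for a share under 0.05. The real count was 0 there for species and for sums (10 of 10 splits each), and the highest other split gave 2 species and 1 sum.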

How the results depend on the processing

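The restriction to libraries of at least 1000 reads was chosen only after the data were seen, and the other alternatives were planned. Of 231 alternatives to 28 results, 181 gave the same direction and side of the threshold, or a count within 1.5 times, as did 210 of 247 fits with 1 mouse left out. A count is scored the same even where the species called or their directions differ. For site in set 2 this was so in libraries of at least 1000 reads, with 12 calls, 7 of them higher, against 8, all lower. The cause of the changes was not tested.

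Depth is a limit: with 13 NMRI libraries under 50 reads, the distal small intestine of set 2 turns with the reads required. In libraries of at least 1000 reads, against all libraries, the distal small-intestinal difference from the cecum in set 2 reversed for C. sporogenes (1.00), C. aerofaciens (0.87), P. penneri (0.50), E. fergusonii (1.02) and P. rettgeri (0.65), and the strain difference on choline minus for P. rettgeri in the distal large intestine (-2.23, where 1 library of 26 reads drops out). That restriction also gave 2 species and 1 sum for diet in C57BL/6J males, 1 sum for diet in NMRI males, 1 species for the interaction and 1 for site in the 5-species mice, in place of 0. The last is E. rectale in the proximal small intestine, where 1 mouse of that group has at least 1000 reads, so it describes 1 library.

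On centred log-ratios both community calls of C. aerofaciens ended (0 calls for 6 against 5 and 0 for 13 against 6 species) with differences of 0.99 and -0.76, against 0.89 and -0.91. Strain gave 1 call on choline plus and 3 on choline minus, and C. sporogenes between 13 and 6 species reversed to 0.37. Also reversed were C. asparagiforme (0.15) and C. hathewayi (0.36) for diet in C57BL/6J males and C. hathewayi (-0.0869) for the interaction, all in the distal large intestine, and for site in set 2 C. sporogenes (0.42), E. fergusonii (0.90) and P. rettgeri (1.86) in the distal small intestine. As a ratio to the core, C. sporogenes stood at 0.29. As shares of the total the core gave 1 call for 13 against 5 and 2 for 13 against 6 species.

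Exact permutation tests per species called 0 in the 6 against 5, 13 against 6, diet in NMRI males, strain on choline plus, strain on choline minus (species and sums) and sex comparisons, and the exact sign-flip test called 0 for site in the 6-species mice. These counts say little about the calls: with smallest p of 0.00794, 0.0286 (strain on choline plus) or 0.0179 (strain on choline minus), adjustment lets exact tests call nothing unless at least 4 tests (communities), 6 (diet in NMRI males, sex), 22 and 14 (strain on choline plus and minus) or 5 (sums) pass together. With 5 mice no sign-flip p is under 0.0625. A pseudocount of 0.001 gave 3 calls for sex and 5 for site in set 2, and reversed P. rettgeri for strain on choline minus in the distal large intestine (-0.65) and for site in set 2 (0.76). A pseudocount of 1e-05 reversed P. penneri for site in set 2 in the distal large intestine (-0.11). Fitting only the groups compared gave 1 call for 13 against 5 species (E. rectale, -1.47), 1 for sex, 1 sum for diet in NMRI males and 0 sums for strain on choline minus. Adjustment within each site gave 2 sums for diet in NMRI males. With 1 fit over sites and mouse as a random block, strain on choline plus gave 4 calls, sex 2, the sums for diet in NMRI males 1 and those for strain on choline minus 1.

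Mouse numbers restart in each group and do not pair mice: in no comparison did every numbered pair correlate above 0.1 (between -0.857 and 0.384). As a replicate block across groups they gave 1 call for strain on choline plus, 1 for sex and 1 sum for strain on choline minus. The R2 with splits inside the replicate block was 0.343 for diet in NMRI males (exact permutation p 0.25), 0.431 for strain on choline minus (p 0.25) and 0.281 for sex (p 0.125). These p say nothing of a loss, since splits inside 3 numbered pairs can give none under 0.25 and inside 4 none under 0.125.

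For R2, the distal small intestine, where nearly all NMRI libraries hold under 50 reads, gave 0.114 for diet in NMRI males (exact permutation p 0.516), 0.173 for strain on choline minus (p 0.286) and 0.132 for sex (p 0.381), and in set 1 0.525 for 13 against 6 species (p 0.0238). The distal large intestine gave 0.430 (exact permutation p 0.00794), 0.478 (p 0.0179) and 0.298 (p 0.00794) for the first 3 of these, 0.401 for strain on choline plus (p 0.0286) and 0.273 for 6 against 5 species (p 0.00794). The Aitchison distance gave 0.481 for strain on choline plus and 0.764 for 13 against 5 species. Square-root shares gave 0.345 and 0.351 for 13 against 5 and 13 against 6 species. Shares of the total gave 0.838 and 0.773 for the same comparisons, but they are affected by the species given only to the 13-species mice. That difference was set by the communities given, so 0.838 and 0.773 cannot show whether the proportions within the core changed.

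With 1 mouse left out, counts of species ranged from 1 to 8 for 13 against 6 species, 0 to 2 for diet in C57BL/6J males, 0 to 1 for the interaction, 1 to 2 for strain on choline plus, 5 to 9 for strain on choline minus, 1 to 7 for sex and 0 to 1 for site in the 5-species mice. Counts of sums ranged from 0 to 1 for diet in C57BL/6J males, 0 to 2 for diet in NMRI males and 0 to 4 for strain on choline minus. R2 ranged from 0.291 to 0.369 for diet in NMRI males, 0.367 to 0.563 for strain on choline minus, 0.196 to 0.538 for sex, 0.158 to 0.359 for 6 against 5 and 0.199 to 0.426 for 13 against 6 species. C. sporogenes between 13 and 6 species ranged from -0.31 to 0.00918. At the distal large intestine, C. hathewayi ranged from -0.70 to 0.0815 and Firmicutes from -0.82 to 0.0140 for diet in C57BL/6J males, C. hathewayi from -0.0101 to 0.78 for the interaction and from -0.11 to 0.68 for strain on choline minus, P. rettgeri from -2.23 to 1.42 for strain on choline minus, and P. penneri from -0.0626 to 0.41 for site in set 2.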

Other observations

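The test of Proteobacteria by gut site in this part was chosen only after its result had been seen, and the other values carry no test.

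The cecal communities of the 13-species C57BL/6J males on choline plus are set side by side without a test, because each set was normalized in its own table. B. caccae made up 34.9% ± 2.79 in set 1 (SD, n = 5) and 36.8% ± 6.24 in set 2 (SD, n = 3), B. thetaiotaomicron 23.1% ± 1.63 and 21.6% ± 0.789, C. aerofaciens 4.48% ± 0.569 and 5.65% ± 1.68, P. penneri 1.58% ± 0.187 and 1.56% ± 0.582, and P. rettgeri 2.00% ± 0.209 and 2.38% ± 0.224. E. tarda had 4.86% ± 0.826 in set 1 and 2.25% ± 0.944 in set 2, and E. rectale 0.238% ± 0.0329 and 0.00419% ± 0.00727, the latter from 1 library. The 8 added species summed to 23.2% ± 2.16 and 24.1% ± 3.16.

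A. hydrogenalis, an anaerobic coccus among the added species, had the lowest cecal mean of the 13 species in set 1. It was listed above 0 in 8 of the 20 libraries of the 13-species mice of set 1, with at most 0.0439%. Mice not given it also list it, in 3 of 20 libraries (6 species) and 3 of 16 libraries (5 species), all small-intestinal, with up to 0.185% and 0.251% in those of at least 1000 reads. In set 2 it was listed in 3 of 9 libraries of the C57BL/6J choline-plus mice and in 1 of 9 of the choline-minus mice. In NMRI males it was listed in 0 of 12 and 0 of 15 libraries on choline plus and minus, whose pooled reads allow up to 0.000636% and 0.000614%. In NMRI females 2 of 15 libraries listed it, and 0 of the 10 libraries of at least 1000 reads did. C. sporogenes had a cecal mean between 0.122% and 0.444% in the 5 groups of set 2. The upper end, in NMRI females, rests on mouse 1 (1.53%) and is 0.173% without it, and the mean of NMRI males on choline minus (0.290%) is 0.152% without mouse 2.

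Community diversity in the cecum, as the Shannon index with natural logarithms, was 1.21 ± 0.0532 in 5-species mice (SD, n = 4), 1.28 ± 0.0645 in 6-species mice (SD, n = 5) and 1.87 ± 0.0397 in 13-species mice of set 1 (SD, n = 5). In set 2 it was 1.86 ± 0.0931 and 1.81 ± 0.0877 in C57BL/6J males on choline plus and minus (SD, n = 3 each), 1.68 ± 0.114 and 1.66 ± 0.112 in NMRI males on choline plus and minus (SD, n = 4 and 5), and 1.84 ± 0.124 in NMRI females (SD, n = 5).

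Proteobacteria may make up more of the distal small-intestinal than of the cecal community in 13-species C57BL/6J mice. The pattern was seen in set 2, where the sum was 41.7% ± 10.8 against 13.4% ± 2.85 (SD, n = 6 each), higher in 6 of 6 mice, with a two-sided exact sign-flip p of 0.0312, the smallest that 6 mice can give. In the 13-species mice of set 1 with at least 1000 reads at both sites it was 19.1% ± 6.63 against 13.3% ± 1.52 (SD, n = 4 each), higher in 3 of 4 mice. The mean log2 difference there was 0.4683 (two-sided exact sign-flip p 0.25, with 0.125 the smallest that 4 mice can give), which leaves the hypothesis undecided.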
